A study of Mus musculus with 4 samples.

How the data were processed

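Tumours grown from Lewis lung carcinoma cells under the skin of C57BL/6 mice were taken 3 weeks after inoculation. Per the labels, tumour pieces were kept for 12 h in serum-free medium that was passed through a 0.2 µm filter, and exosomes for RNA were collected with a precipitation reagent without ultracentrifugation. Total RNA was ligated to adaptors at both ends, amplified by reverse transcription and PCR, size-selected on a gel and sequenced. There were 4 libraries in 2 groups, 2 of tumour-derived exosomes and 2 of primary tumour, and groups were taken from the labels.

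Per the file headers, each library has a count and an FPKM per gene, and the authors' processing notes name TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff against the mouse assembly GRCm38. The deposited counts are whole numbers with no normalization. The deposited FPKM were scaled by the authors to gene length and to each library's own total, since the count divided by gene length and library total gave every FPKM within 0.0822%. Which tool made the counts, the gene annotation, the treatment of reads with several matches and the strand setting are not given in the sources used here. The tables of the 4 samples equal the columns of the series table. FPKM had been expected before the data were examined, with a count test set as the rule if counts were held, and that rule was followed. Of 47069 gene IDs, 14421 had a count, and 46574 had a symbol and biotype in the GENCODE M21 annotation. The other 495 held 0.00555% of exosome counts and 0.00208% of tumour counts.

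Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15, which came to 1.79 CPM in at least 2 libraries) and the two-sided quasi-likelihood test, with group as the only term and Benjamini-Hochberg adjustment over the 1442 genes tested at 0.05. TMM factors were 2.41 and 2.93 for exosomes and 0.388 and 0.365 for tumour. One count in an exosome library is 3.27 or 4.60 CPM. A gene with 1 count in each therefore passes the filter if its total over all libraries is at least 15. Differences are log2, exosomes minus tumour, and folds against a group at 0 use a floor of 3 counts per library. The SE given for an edgeR difference is its absolute value divided by the square root of the test's F statistic. It was not estimated separately and depends on the fit. Shares are percentages of all gene counts, with exact Clopper-Pearson 95% intervals for single libraries. Annotated small RNA genes with a count whose transcripts were at least 90% identical over at least 80% of the longer sequence (blastn 2.17.0) were summed to families.

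Before the data were examined, 36 gene lists were fixed. They cover spliceosomal small nuclear RNAs, small nucleolar and Cajal body RNAs, other structured noncoding RNAs, microRNA loci, ribosomal RNA loci, mitochondrial messenger and transfer RNAs, nuclear long noncoding RNAs, small RNA host genes, histones, ribosomal proteins, translation factors, oxidative phosphorylation, the proteasome, exosome marker proteins, glycolysis and hypoxia, immediate early genes, heat shock and the unfolded protein response, interferon response, RNA sensing, chemokines and cytokines, premetastatic niche factors, extracellular matrix, cell cycle, class I histocompatibility genes, and markers of epithelial and carcinoma cells, macrophages and monocytes, neutrophils, T and natural killer cells, B and plasma cells, dendritic cells, fibroblasts and pericytes, endothelium, erythroid cells and platelets, skeletal muscle, and skin and adipose tissue. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 20 lists tested, with an estimated correlation and fry beside it. Named genes were fixed by rule, also before: the 8 largest fitted differences in each direction past the threshold among genes outside the small noncoding patterns and unnamed loci, with at least 10 counts in both libraries of the higher group, the 4 largest in each direction among the rest, up to 3 tested members with the highest mean of each list, and a set of genes named in advance. This gave 103 tested genes. The leading genes of each library and the RNA families were chosen after their values were seen.

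Alternatives set in advance were DESeq2 1.42.0, median-of-ratios scaling, scaling by summed FPKM with and without the listed RNA classes, quantile normalization, limma on log2 FPKM with other pseudocounts, other filters, a replicate block, each library left out, no abundance trend, robust estimation, a minimum length of 300 bases, removal of a length trend and a minimum difference of 1. Chosen after seeing the data were scaling to library totals, limma on log2(FPKM + 1), TMMwsp, summing or averaging copies, thinning the tumour libraries to exosome depth, at least 10 counts in at least 2 libraries, leaving out small nucleolar RNA genes, detection at equal depth and classes by biotype. Tested on simulated data in 10 runs, the test called 53.8% of genes shifted by 2 on the log2 scale, 70.1% of those shifted by 4 and 0.346% of unshifted genes. In 50 runs with lists of 20 genes shifted by 2, camera called 100% of shifted and 2% of unshifted lists at an unadjusted p under 0.05. Genes were drawn independently and most were unshifted, so these rates need not hold for correlated genes or large shifts in composition. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No deposited library was left out.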

Results

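Lewis lung carcinoma is an established mouse lung carcinoma cell line that forms tumours under the skin of C57BL/6 mice. Tumours were taken 3 weeks after inoculation, and gene counts were available for 2 libraries of RNA from exosomes released by tumour pieces in culture and 2 libraries of RNA from primary tumour. The comparison asked which gene signatures differ between the tumour and the exosomes derived from it. The exosome libraries held 305751 and 217201 counts over 47069 annotated genes, and the tumour libraries held 14543691 and 10849811, so that the tumour group had 48.6 times as many counts in all. The replicates are described only as replicates, so p-values measure only the spread between these libraries, and the labels do not say whether they come from separate animals. Counts come from amplified reads without molecular identifiers, and intervals and floors below cover counting error only.

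The 2 kinds of library were filled by different classes of small RNA. Small nuclear RNA, the RNA of the splicing machinery, made up 49.9% ± 1.35 (SD, n = 2) of exosome counts and 0.488% ± 0.0365 of tumour counts. Small nucleolar RNA, which guides the modification of ribosomal RNA, showed the opposite arrangement, with 0.909% ± 0.0230 of exosome counts and 81.9% ± 0.921 of tumour counts. The ribozyme class, which is mostly the RNA of ribonuclease P, took 25.8% ± 4.53 of exosome counts and 0.0136% ± 0.00197 of tumour counts. Ribosomal RNA genes, nearly all of them 5S, held 15.6% ± 2.35 against 0.372% ± 0.0271. Small nuclear and 5S RNA genes have many near-identical copies, and reads counted at every copy would raise these shares. Mitochondrial transfer RNA held 0.231% ± 0.00166 of exosome counts and 1.67% ± 0.411 of tumour counts. Protein-coding genes held 3.06% ± 0.3328 and 1.57% ± 0.0173. The microRNA class of the annotation held 1.51% ± 0.308 and 12.1% ± 0.320, and in the tumour it was almost wholly Snord43, a small nucleolar RNA by its symbol that carries the microRNA biotype and alone held 12.2% and 11.8% of the tumour libraries. In exosomes, n-TStga1, a transfer RNA gene by its symbol, had 1694 and 1075 of the 3958 and 3757 counts of this class. Loci with a microRNA symbol went the other way from the class, with 0.845% ± 0.389 of exosome counts and 0.143% ± 0.00607 of tumour counts.

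**Figure D1:**
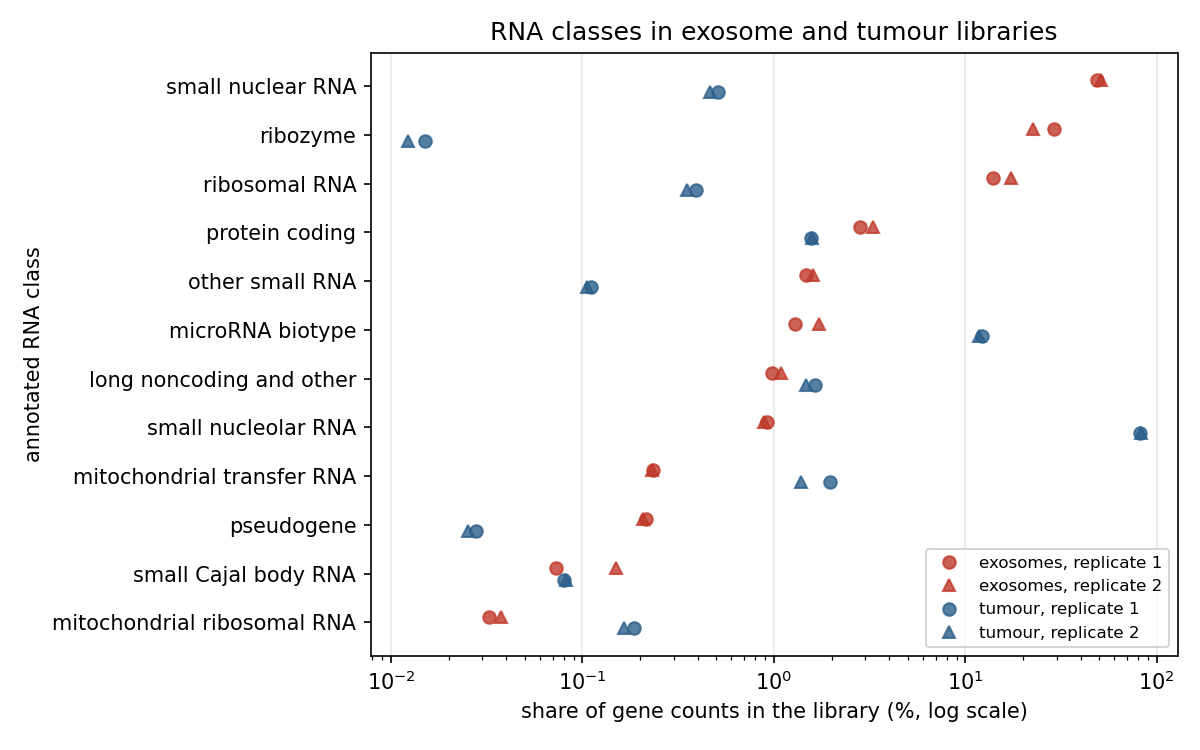
Share of gene counts (%, log scale) held by each annotated RNA class in the 2 exosome libraries (red) and the 2 tumour libraries (blue), 1 point per library. Small nuclear RNA lies at 49.0% and 50.9% in exosomes and at 0.513% and 0.462% in tumour, and small nucleolar RNA at 0.925% and 0.893% against 81.2% and 82.5%.

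For each class the exact binomial 95% intervals of the single libraries were narrow, for example 48.8% to 49.2% for small nuclear RNA in exosome replicate 1 and 0.510% to 0.517% in tumour replicate 1. With 2 libraries against 2, an exact two-sided permutation test cannot reach 0.05 (the smallest p it can give is 0.33), so the shares are described and not tested. A few genes dominated each kind of library. Rpph1 (chromosome 14, 50807449 to 50807767, GRCm38), the RNA component of ribonuclease P, alone held 27.9% and 21.6% of the exosome counts. In the tumour libraries the leading gene was Snord55 (chromosome 4, 117155770 to 117155848), with 19.9% and 20.2%, followed by Snord43 and, with 9.89% and 11.5%, Snord49a.

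Many small RNA genes have near-identical copies whose reads cannot be assigned with certainty, so copies were summed to families. The U1 family, the small nuclear RNA that recognises the 5' splice site, rose from 0.0409% ± 0.0118 of tumour counts to 30.4% ± 4.19 of exosome counts (SD, n = 2), a 742-fold difference between the shares, or 9.54 on the log2 scale with library totals. How reads with several matches were counted is not given, and sums overstate shares if such reads were counted at every copy. With the mean per copy in place of the sum, U1 held 2.20% of the averaged exosome counts and 0.00115% of the averaged tumour counts. U2, 5S and RNase P RNA, which has 1 copy, then held 3.59%, 0.589% and 65.5% in exosomes. With TMM scaling and copies summed, which the values that follow use, the log2 difference of U1 was 6.82 (SE 0.22, edgeR adjusted p = 1.79e-18). Averaged per copy it was 6.80. The U2 family, which binds the branch point, rose by 5.09 (SE 0.22, edgeR adjusted p = 2.67e-16). The U5 family moved the other way and fell by 5.64 (SE 0.23, edgeR adjusted p = 1.22e-16), although U1, U2 and U5 all belong to the major spliceosome. RNase P RNA rose by 8.41 (SE 0.25), RNase MRP RNA, a related ribonuclease RNA, by 6.06 (SE 0.25), telomerase RNA by 4.55 (SE 0.29), 7SL, the RNA of the signal recognition particle, by 4.04 (SE 0.22), vault RNA by 3.28 (SE 0.24) and 5S ribosomal RNA by 2.74 (SE 0.17). The 7SK RNA, which holds the elongation factor P-TEFb inactive, fell by 5.74 (SE 0.30), 5.8S ribosomal RNA fell by 4.15 (SE 0.32) and Y3 RNA by 3.45 (SE 0.32). U13, a small nucleolar RNA, had 1 count in each exosome library against 888 and 664 in tumour. The size of these p-values and SEs depends on the set of features fitted together. RNase P RNA had edgeR adjusted p = 2.66e-19 (SE 0.25) here. With the same counts in the fit of single genes it had edgeR adjusted p = 3.41e-07 (SE 0.33).

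**Figure D2:**
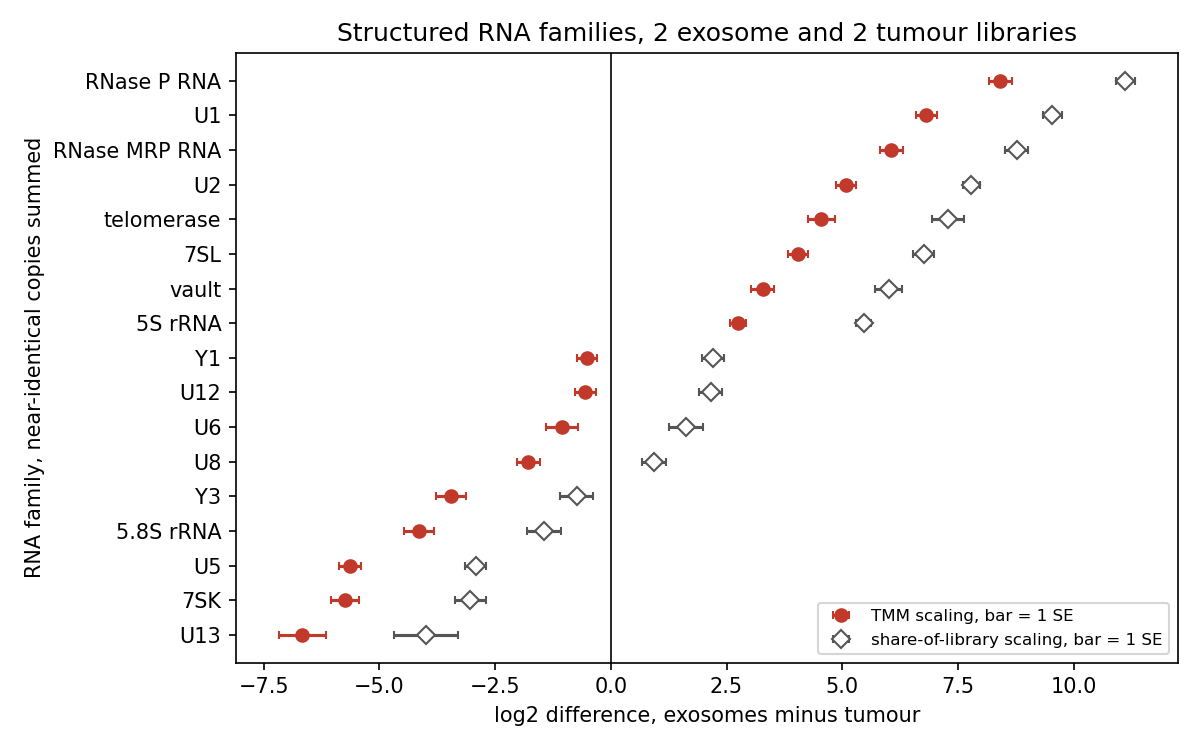
Log2 difference between exosome and tumour libraries (2 against 2) for structured RNA families, with near-identical copies summed, after TMM scaling (filled circles) and with scaling to library totals (open diamonds); bars are 1 SE. RNase P RNA lies at 8.41 and 11.11 and 7SK at −5.74 and −3.03, while U6, U8, U12 and Y1 lie below 0 with TMM and above 0 with library totals.

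These differences are relative to the typical tested gene, as TMM scaling sets it. Of 911 tested protein-coding genes other than histones, only 223 reached the filter level in both tumour libraries, so most were admitted through exosome counts. Requiring at least 10 counts in at least 2 libraries, also chosen after seeing the data, gave a median log2 difference of −0.51 over the genes then tested. Scaling to library totals, an alternative chosen after seeing the data, moved the median log2 difference of all tested genes from 0.018 to 2.75. U1, U2, RNase P RNA, RNase MRP RNA, telomerase RNA, 7SL, vault RNA and 5S were higher in exosomes and U5, 7SK, 5.8S and U13 lower under TMM and library totals alike. Because library totals move differences upward, only the lower families were put to a test by this change. The sign turned for U6 (−1.05 with TMM and 1.62 with library totals), for U8 (−1.78 and 0.93), for U12 (−0.55 and 2.16) and for Y1 (−0.51 and 2.20). Of these, U12 and Y1 were not called with TMM (edgeR adjusted p = 0.0680 and 0.0607). Y3 had −0.74 with library totals (edgeR adjusted p = 0.0648), and it turned to 0.42 after scaling by summed FPKM and to 1.47 with the tumour libraries thinned to exosome depth. The 5.8S family turned to 0.72 with thinned tumour libraries.

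Gene by gene, 1442 genes had enough counts to be tested. Of these, 230 were higher in exosomes and 318 lower by edgeR's quasi-likelihood test at an adjusted p of 0.05. With library totals in place of TMM the split was 920 higher and 166 lower, with 1099 higher and 124 lower after scaling by summed FPKM, and with 1011 and 148 when the listed noncoding, mitochondrial and ribosomal protein genes were left out of that sum. All 230 genes called higher with TMM were called higher with library totals too, and 166 of the 318 called lower were called lower, while 25 turned to higher. Library totals moved the median log2 difference up by 2.76, so the higher calls could hardly be lost and their number says nothing about stability. By class, 50 of 69 small nuclear RNA genes were higher and 11 lower, 50 of 63 ribosomal RNA genes were higher and 9 lower, and 126 of 148 small nucleolar RNA genes were lower and 3 higher. With library totals 59 small nuclear RNA genes were higher and 8 lower, and 61 ribosomal RNA genes were higher and 1 lower. Of small nucleolar RNA genes 101 were then lower and 16 higher. Near-identical copies of U1 (37 genes with counts), U2 (13) and 5S (71) share reads and are counted singly here. With copies summed, 157 of 1315 features were higher and 305 lower with TMM. Among 954 protein-coding genes, 51 were higher and 100 lower with TMM, against 660 higher and 17 lower with library totals, so the direction of most coding genes rests on the scaling. The filter admits a gene on a single count in each exosome library if its total over all libraries is at least 15. Of the called genes, 285 had under 10 counts in both exosome libraries.

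Among genes whose symbols match the small noncoding patterns or carry no gene name, those with the highest fitted positive differences were Rpph1 and 3 copies of U1 with no count in either tumour library, for which the fitted value sets no rank. Gm22155 (chromosome 6, 6924118 to 6924279) had 147 and 117 exosome counts and was at least 302-fold higher, Gm25587 at least 57.9-fold and Gm25581 at least 36.0-fold, against a floor of 3 counts per library after TMM scaling. Reads of U1 copies are shared, so these values are uncertain for the single copy. Rpph1 rose by 8.34 (SE 0.33, edgeR adjusted p = 3.41e-07). The fitted differences furthest below 0, which set no rank among genes with 0 or 1 exosome counts, were those of Snord98, Snord11, Snord7 and Gm24253. Snord98, Snord11 and Snord7 had no count in the exosome libraries and were at least 228-fold, 137-fold and 95.5-fold lower with TMM and 32.4-fold, 19.5-fold and 13.6-fold lower with library totals. Gm24253 had 1 and 0 exosome counts against 29234 and 20227 in tumour.

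Of the remaining named genes, n-TStga1 had the largest positive difference (9.37, SE 0.28, edgeR adjusted p = 1.10e-07), with 1694 and 1075 exosome counts against 18 and 11. By its symbol n-TStga1 is a serine transfer RNA gene (chromosome 13, 23518142 to 23518250) that carries the microRNA biotype, and 92.1% of the annotated small RNA Gm44456 is identical to part of it. Summed with its near-identical copy n-TSaga9, the counts were 1705 and 1084 in exosomes against 49 and 25 in tumour. Reads of the 2 copies may be shared, so the value of 9.37 is uncertain for the single copy. Yipf1, a gene of a Golgi membrane protein family (chromosome 4, 107314363 to 107359823), followed with 4.70 (SE 0.35, edgeR adjusted p = 1.37e-05), and its 884 and 1568 exosome counts differed between replicates. A Yipf1 transcript holds a stretch 94.3% identical to 98.4% of the annotated small RNA Gm23413, so its counts cannot be taken as messenger RNA alone. Nfix, a transcription factor, rose by 3.23 (SE 0.66) on 10 and 12 exosome counts, the ribosomal protein gene Rps15 by 2.87 (SE 0.38), and the basement membrane collagen gene Col4a1 by 2.13 (SE 0.37). Igfbp4, Noct and Eef2 were higher by 1.46, 1.29 and 1.01 with adjusted p = 0.00966, 0.0136 and 0.0230 by edgeR. The Igfbp4 and Noct calls were lost without exosome replicate 1 (1.25 and 1.09), without tumour replicate 1 (1.37 and 1.12) or without tumour replicate 2 (1.52 and 1.43). The Eef2 call was lost without exosome replicate 1 (0.78) or tumour replicate 2 (0.75), and its value turned to −0.17 with no filter and to −0.84 with a mean FPKM of at least 5. Eef2 overlaps Snord37, and transcripts of Igfbp4 and Noct hold stretches like annotated small RNAs, 83.9% identical to Gm27773 and, on the opposite strand, 86.0% identical to Gm22002.

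Snrpb, the gene of a core spliceosomal protein (chromosome 2, 130171414 to 130179403), fell by 10.27 (SE 0.24, edgeR adjusted p = 7.80e-08), from 146964 and 114981 tumour counts to 16 and 14 in exosomes. Its tumour counts, 65.1% and 67.2% of all protein-coding counts, compare with 385 and 251 for Actb, so they cannot be taken as messenger RNA alone, although no annotated small RNA gene overlaps it. Rpl7a fell by 8.91 (SE 0.24, edgeR adjusted p = 8.89e-08), and 3 annotated small RNA genes lie within it, so its counts cannot be taken as messenger RNA alone. The mitochondrial gene mt-Atp8 had no exosome count and was at least 19.2-fold lower with TMM and 2.73-fold with library totals. Secisbp2, which acts in selenoprotein synthesis, was at least 5.15-fold lower. The histone genes Hist1h3h, Hist1h3c, Hist1h2bg and Hist1h4f were at least 6.19-fold, 4.09-fold, 3.18-fold and 2.95-fold lower. With library totals, the tumour levels of Secisbp2 and these 4 histone genes lay under the exosome floor, and no fold could be given.

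Of 36 gene lists fixed before the data were examined, 20 had at least 5 tested members, and 8 of those passed camera with a preset correlation. Camera with an estimated correlation passed 0 of them, with 3 at an unadjusted p under 0.05, and fry passed 7. With near-identical copies summed 6 passed. The list of small nucleolar and Cajal body RNAs had 64 of 70 members lower and 1 higher, with 66 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.30e-32, and adjusted p = 0.198 with an estimated correlation), and with library totals 53 were lower and 6 higher. Its most abundant members, Snord55, Snord43 and Snord49a, stood at −10.01, −9.5 and −9.92. Among spliceosomal small nuclear RNAs, 5 of 7 rose and 1 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.00599, and adjusted p = 0.347 with an estimated correlation), led by Rnu1b6 at 7.32, Rnu1a1 at 6.76 and Rnu2-10 at 4.93. With library totals 6 rose and 1 fell. With copies summed the small nuclear RNA list came to 5 features, 2 higher and 2 lower, and did not pass (camera adjusted p = 0.854). Because most U1 and U2 copies have no family symbol, the list as fixed held only 5.56% ± 0.313 of exosome counts (SD, n = 2).

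Ribosomal RNA loci had 41 of 53 members higher and 9 lower, unaltered when adjusted over the list alone (adjusted p = 5.97e-15, and adjusted p = 0.198 with an estimated correlation), and the near-identical 5S copies n-R5s33, n-R5s105 and n-R5s139 rose by 3.42, 2.76 and 2.69. With library totals 51 of these loci were higher and 2 lower. Reads are shared among the 71 5S copies with counts, and with copies summed, an alternative chosen after seeing the data, the list came to 5 features, 3 higher and 2 lower, and did not pass (camera adjusted p = 0.879). Other structured noncoding RNAs had 7 of 11 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.595 with an estimated correlation), including Rmrp at 5.98, Rn7s1 at 4.01 and Rn7sk at −5.81, and 9 were higher and 1 lower with library totals. Of 44 microRNA loci, 33 rose and 8 fell, and 34 rose and 8 fell when adjusted over the list alone (adjusted p = 5.84e-05, and adjusted p = 0.595 with an estimated correlation; fry gave adjusted p = 0.0602), and with library totals 37 rose and 3 fell. Mir10b rose by 3.66 (SE 0.34) and Mir181a-1 by 4.54 (SE 0.21), while Mir5099 had 1 and 0 exosome counts against 10152 and 6625 in tumour.

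Of 13 mitochondrial messenger RNAs, 11 fell and 0 rose, and 13 fell when adjusted over the list alone (adjusted p = 6.85e-05, and adjusted p = 0.304 with an estimated correlation). Mt-Nd4 fell by 2.74 and mt-Co1 by 3.79, and mt-Nd5 had −0.68 (edgeR adjusted p = 0.112). With library totals 2 of the list rose and 7 fell, with mt-Nd4 at 0.028, mt-Nd5 at 2.09 and mt-Co1 at −1.03. Of 21 mitochondrial transfer RNAs, 19 fell, and 20 when adjusted over the list alone (adjusted p = 2.26e-08, and adjusted p = 0.497 with an estimated correlation), with mt-Ts2 at −5.93, mt-Th at −7.12 and mt-Tv at −6.90, and with library totals 15 fell and 1 rose. Of 43 replication-dependent histone genes, 37 fell and 0 rose, and 40 fell when adjusted over the list alone (adjusted p = 7.33e-07, and adjusted p = 0.330 with an estimated correlation). Hist1h4d had 1 and 1 exosome counts against 1663 and 1417 in tumour, Hist1h4a had 1 and 0 against 204 and 181, and Hist1h4c fell by 3.27. With library totals only 6 histone genes fell and 0 rose. The histone median was −4.18 as fitted and −2.63 with the 14 genes that lack counts in one group set at their bound; the small nucleolar median was −9.26 and −8.11, and the mitochondrial transfer RNA median −5.23 and −4.16.

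**Figure D3:**
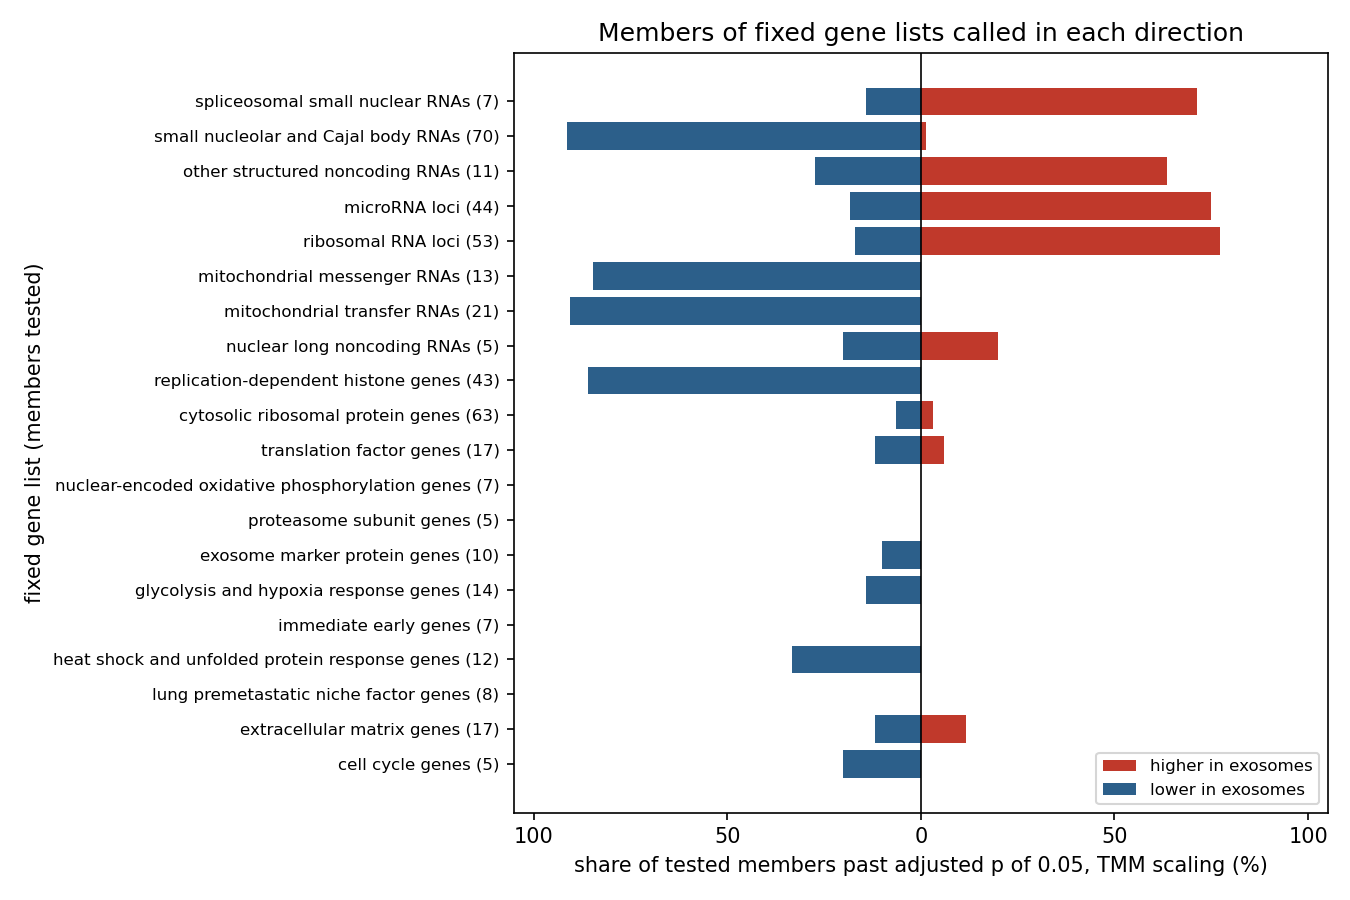
Share of the tested members of each fixed gene list with at least 5 tested members that were called higher (red, to the right) or lower (blue, to the left) in exosomes at an adjusted p of 0.05 with TMM scaling; the number tested stands in parentheses. Of 70 small nucleolar and Cajal body RNAs 64 were lower, while of 53 ribosomal RNA loci, most of them near-identical 5S copies, 41 were higher.

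The other 12 tested lists did not pass camera. Cytosolic ribosomal protein genes had 2 of 63 members higher and 4 lower (1 and 2 when adjusted over the list alone), among them Rps3a1, which fell by 2.51, contains Snord73a and had 0.27 with library totals, where 46 members rose and 1 fell. Translation factor genes had 1 of 17 higher and 2 lower, as when adjusted over the list alone, and Eef1a1 and Pabpc1 stood at −0.14 and −0.04. Heat shock and unfolded protein response genes had 4 of 12 lower and 0 higher, as when adjusted over the list alone, including Canx at −2.41 and Hspa8 at −1.23. Canx and Hspa8 turned to 0.36 and 1.54 with library totals, and the Hspa8 call was lost without exosome replicate 2 (−1.12), tumour replicate 1 (−1.07) or tumour replicate 2 (−1.36). Glycolysis and hypoxia response genes had 2 of 14 lower, and 0 when adjusted over the list alone, with Ldha at −1.14, Pkm at −0.64 and Tpi1 at 0.49; the Ldha call was lost without any one of the 4 libraries (exosome replicate 1 −1.04 and 2 −1.26, tumour replicate 1 −1.0 and 2 −1.25) and turned to 1.63 with library totals. Extracellular matrix genes had 2 of 17 higher and 2 lower, and 2 higher and 0 lower when adjusted over the list alone, with Fn1 at −0.56 and Col3a1 at 0.56. Nuclear long noncoding RNAs had 1 of 5 higher and 1 lower, as when adjusted over the list alone, with Neat1 at −0.54 and Pvt1 at 0.90. The lower one was Malat1, which fell by 1.69 with TMM and had 1.08 with library totals. Cell cycle genes had 1 of 5 lower, and 0 when adjusted over the list alone, with Tubb5 at −0.28 and Mki67 at −0.27. The lower one was Top2a, with 1 and 1 exosome counts against 59 and 26, whose call was lost without exosome replicate 1 (−2.42), exosome replicate 2 (−2.64) or tumour replicate 1 (−2.10). For exosome marker protein genes 1 of 10, Hspa8, was lower, and 0 when adjusted over the list alone, with Hsp90ab1 at −0.44 and Anxa2 at 0.77, and 8 of the 10 were higher with library totals. By edgeR 0 members were called, over all genes or over the list alone, of 8 lung premetastatic niche factor genes, 7 immediate early genes, 7 nuclear-encoded oxidative phosphorylation genes and 5 proteasome subunit genes, of which 2, 1, 0 and 2 had an unadjusted p under 0.05, with for example Jun at 0.88, Myc at −1.47, Ndufs7 at −0.45 and Psma6 at 1.68. With library totals 14 of 17 translation factor genes, 14 of 17 extracellular matrix genes and 8 of 8 premetastatic niche factor genes rose, as did 8 of 14 glycolysis and hypoxia, 6 of 12 heat shock, 6 of 7 oxidative phosphorylation, 5 of 7 immediate early, 3 of 5 proteasome, 3 of 5 cell cycle and 3 of 5 nuclear long noncoding RNA genes, and none of these lists had a member that fell, so directions in these lists rest on the scaling.

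Messenger RNA of cell type markers was thin in exosomes, and lists with under 5 tested members are described by values. Among haemoglobin genes, Hbb-bs had 22 and 35 exosome counts and 506 and 249 tumour counts (−0.85), and Hbb-bt stood at −0.72 and Hba-a1 at −1.08 (adjusted p = 0.00928 by edgeR); 2 of 4 erythroid and platelet markers were lower, and 4 when adjusted over the list alone. With library totals all 4 were higher, and the Hba-a1 call with TMM was lost without tumour replicate 1 (−0.97). With TMM no member was called among 4 macrophage and monocyte markers (Lyz2 −0.02, Arg1 0.97), 2 neutrophil markers (S100a8 0.99, S100a9 2.16), 2 fibroblast and pericyte markers (Col3a1 0.56, Col1a1 1.80), 2 epithelial and carcinoma markers (Vim 0.65, or −1.20 with a mean FPKM of at least 5, and Krt18 −0.07), 1 endothelial marker (Cdh5 1.54), 1 dendritic and class II marker (Cd74 −0.17), 1 skeletal muscle marker (Acta1 1.22), 3 class I histocompatibility genes (H2-D1 0.46, B2m −0.79), 4 chemokine and cytokine genes (Spp1 −0.24, Tgfb1 −0.31, Il1b 1.22), 1 interferon response gene (Ifitm3 −0.11) and 1 RNA-sensing gene (Eif2ak2 −1.03). With library totals 3 of the 4 macrophage and monocyte, both neutrophil, both fibroblast, the endothelial, the dendritic, the skeletal muscle, 1 of 2 epithelial, 2 of 3 class I, 3 of 4 chemokine and the interferon response genes were higher, with S100a9 at 4.92. Among 3 small RNA host genes 2 were lower, as when adjusted over the list alone, Gas5 with 0 and 1 exosome counts against 31 and 24, and Snhg5 with none against 53 and 41, and both contain annotated small nucleolar RNA genes. The Gas5 call was lost without exosome replicate 1 (−1.82). Snhg5 was at least 2.21-fold lower with TMM. With library totals neither was called, Gas5 stood at −0.18, and no fold could be given for Snhg5, whose tumour level lay under the exosome floor. No T and natural killer cell, B and plasma cell, or skin and adipose marker had enough counts to be tested.

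Genes fixed by name because of their place in exosome biology or lung inflammation were mostly too low to compare. Tlr3, a receptor for double-stranded RNA, had 0 and 1 exosome counts and 1 and 1 tumour counts. The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 had 0 and 0, and 0 and 5, against 6 and 5, and 8 and 1 in tumour, and Ccl2 had 1 and 0 against 7 and 7. The tetraspanin genes Cd9, Cd63 and Cd81, whose proteins mark exosomes, had 1 exosome count between them against 7 and 7, 8 and 7, and 4 and 4 in tumour, and Tsg101 had none against 2 and 0. The floor of 3 counts was 9.81 and 13.8 CPM in the exosome libraries and 0.206 and 0.277 CPM in the tumour libraries, so lower levels of these messenger RNAs in exosomes were not detectable at this depth. Among those tested, Actb stood at 0.19 (SE 0.18, adjusted p = 0.510 by edgeR), Gapdh at −0.53 (SE 0.45, adjusted p = 0.458) and Pdcd6ip at 0.36 (SE 0.59, adjusted p = 0.801). With library totals all 3 were called higher, Actb at 2.97, Gapdh at 2.24 and Pdcd6ip at 3.11 (edgeR adjusted p = 3.60e-12, 0.00161 and 0.00332). Actb turned to −0.99 with no filter and to −1.65 with a mean FPKM of at least 5.

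The deeper tumour libraries had more genes with a count, 10994 and 9616 against 5433 and 4115 in exosomes. At an FPKM of at least 1 the order turned, with 2485 and 2355 genes in exosomes and 875 and 796 in tumour. A single count is 3.27 and 4.60 CPM in exosomes and 0.0688 and 0.0922 CPM in tumour. Far fewer counts therefore reach this FPKM in exosomes, and the 2 groups are not compared on a like limit. At the depth of the smallest library, 217201 counts, 4328 and 4115 genes were expected in the exosome libraries and 1092 and 1038 in the tumour libraries. Of the protein-coding counts of the tumour libraries, Snrpb alone held 65.1% and 67.2%. With 1513 protein-coding genes left out, those of highest count and those that overlap annotated small RNA genes, a choice made after seeing the data, 2751 and 2569 of the other protein-coding genes were expected in exosomes and 2338 and 2309 in tumour at 4023 counts.

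Across 1777 genes with a mean FPKM of at least 1, log2(FPKM + 1) correlated between the tumour replicates with Pearson r = 0.994 and Spearman rho = 0.923, and between the exosome replicates with r = 0.789 and rho = 0.359. Between an exosome and a tumour library r lay between 0.557 and 0.607 and rho between 0.321 and 0.380, a range that holds the rho of the exosome replicates. Over the 780 genes with a mean FPKM of at least 5, rho was 0.718 between the exosome replicates and 0.406 to 0.447 between an exosome and a tumour library. These are correlations across genes, which are not independent replicates. The SD of the log2 difference between replicates was 2.56 in exosomes and 0.42 in tumour. The tumour libraries were far deeper and replicates were not compared at equal depth, so depth cannot be told apart from reproducibility here. Replicate counts differed by more than sampling noise, with a chi-square of 28.4 per degree of freedom in exosomes and 33.3 in tumour, so no library was a copy of another.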

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

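Scaling to library totals, limma on log2(FPKM + 1), thinned tumour libraries, small nucleolar RNA genes left out, TMMwsp, the minimum of 10 counts, copies summed or averaged and detection at equal depth were chosen after seeing the data. Against 230 genes higher and 318 lower, 548 in all, leaving out each library gave 206 to 233 higher and 309 to 324 lower, and DESeq2 gave 208 and 299. The replicate block gave 589 genes, 244 higher and 345 lower, although the labels do not say whether equal numbers pair the samples. Summing copies gave 157 higher and 305 lower of 1315 features tested, and averaging them 155 and 304 of 1310. The counts were 920 higher and 166 lower (1086) with library totals, 1099 and 124 (1223) with summed FPKM, and 1011 and 148 (1159) with summed FPKM without the listed RNA classes. With limma on FPKM, which changes the tool and the unit with the pseudocount, they were 661 higher of 887 with 0.1, 494 higher and 204 lower with 1, and 346 higher and 184 lower with 5. They were 825 with 610 lower with no filter (14421 genes tested), 238 with 81 higher and 157 lower for genes of at least 300 bases (1067 tested), 290 with 123 lower with thinned tumour libraries (312 tested), and 185 lower with small nucleolar RNA genes left out (684 tested), settings that change the number of genes tested. Of 56 called named genes, 48 kept call and direction in all 4 fits that leave out a library.

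Against 8 lists past the threshold, 16 passed with no filter, 3 with thinned tumour libraries, where 6 lists could be tested, and 0 with an estimated correlation, and 8 passed without any one library. With copies summed 6 passed, since ribosomal RNA loci and spliceosomal small nuclear RNAs fell to 5 features each (adjusted p = 0.879 and 0.854). Of the alternatives run for each list, the small nucleolar list kept its direction and call in 21 of 22, mitochondrial transfer RNAs in 21 of 22, ribosomal RNA loci in 20 of 22, mitochondrial messenger RNAs and histones in 20 of 21, other structured RNAs in 18 of 22, small nuclear RNAs in 17 of 22 and microRNA loci in 16 of 22. Lists were not run with DESeq2, the minimum difference of 1 or the trend, robust, length and mean-per-copy settings. Ribosomal protein genes passed in the opposite direction with limma on FPKM at pseudocounts of 0.1, 1 and 5 (adjusted p = 0.00989, 0.0134 and 0.0423), as did translation factors and exosome markers with no filter (adjusted p = 1.57e-05 and 0.0223), and the cause was not tested. Without ribosomal RNA loci and mitochondrial genes in the total, the small nuclear list held 6.40% of exosome counts and the small nucleolar list 0.911% of exosome and 65.9% of tumour counts. Genes detected were on average 4765 in exosomes and 2934 in tumour at an FPKM of 0.1, 864 and 493 at an FPKM of 5, and 4221 in exosomes with a count at equal depth. With log2(FPKM + 0.1) replicates correlated at 0.591 in exosomes and 0.981 in tumour.

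Values follow for genes and families whose sign turned and that were called in the test reported or in the alternative; where neither was called a turned sign is not given. The median log2 of all tested genes, 0.018 in the test reported, was 2.75 with library totals, 3.91 and 3.18 with summed FPKM with and without the listed classes, 2.64, 1.47 and 0.62 with limma on FPKM at 0.1, 1 and 5, 2.04 with thinned tumour libraries, −1.86 with no filter, −1.28 with a mean FPKM of at least 5 and 0.38 with quantile normalization. The cause of the single reversals was not tested further. With scaling to library totals the reversed log2 values were mt-Nd5 2.09, mt-Nd4 0.028, Malat1 1.08, Neat1 2.23, Rps3a1 0.27, Eef1a1 2.65, Pabpc1 2.74, Ndufs7 2.33, Hsp90ab1 2.33, Hspa8 1.54, Pkm 2.15, Ldha 1.63, Canx 0.36, Ifitm3 2.64, Spp1 2.53, Tgfb1 2.45, Fn1 2.22, Tubb5 2.49, Mki67 2.50, Top2a 0.22, Lyz2 2.75, Cd74 2.58, Hbb-bs 1.95, Hbb-bt 2.07, Hba-a1 1.72, Gapdh 2.24, U6 1.62, U12 2.16, Y1 2.20 and U8 0.93. With scaling by summed FPKM the reversed log2 values were mt-Nd5 3.25, mt-Nd4 1.19, mt-Co1 0.13, Malat1 2.25, Neat1 3.39, Gas5 0.98, Hist1h4c 0.65, Rps3a1 1.43, Eef1a1 3.80, Pabpc1 3.90, Ndufs7 3.49, Hsp90ab1 3.50, Hspa8 2.70, Pkm 3.30, Ldha 2.79, Myc 2.45, Canx 1.52, Ifitm3 3.80, Eif2ak2 2.87, Spp1 3.69, Tgfb1 3.61, Fn1 3.38, Tubb5 3.65, Mki67 3.65, Top2a 1.37, B2m 3.12, Krt18 3.82, Lyz2 3.91, Mrc1 3.64, Cd74 3.74, Hbb-bs 3.11, Hbb-bt 3.23, Hba-a1 2.87, Gapdh 3.40, U6 2.79, U12 3.32, Y1 3.36, Y3 0.42 and U8 2.09. With scaling by summed FPKM without the listed RNA classes the reversed log2 values were mt-Nd5 2.51, mt-Nd4 0.45, Malat1 1.51, Neat1 2.65, Gas5 0.24, Rps3a1 0.69, Eef1a1 3.07, Pabpc1 3.16, Ndufs7 2.75, Hsp90ab1 2.76, Hspa8 1.96, Pkm 2.56, Ldha 2.05, Canx 0.78, Ifitm3 3.06, Spp1 2.95, Tgfb1 2.87, Fn1 2.64, Tubb5 2.91, Mki67 2.92, Top2a 0.64, B2m 2.39, Krt18 3.08, Lyz2 3.17, Mrc1 2.90, Cd74 3.002, Hbb-bs 2.37, Hbb-bt 2.49, Hba-a1 2.13, Gapdh 2.66, U6 2.06, U12 2.58, Y1 2.62 and U8 1.35. With limma on log2(FPKM + 0.1) the reversed log2 values were mt-Nd5 2.01, Malat1 1.04, Rps3a1 0.26, Eef1a1 2.64, Pabpc1 2.69, Hsp90ab1 2.26, Hspa8 1.46, Pkm 2.11, Ldha 1.60, Canx 0.25, Spp1 2.38, Fn1 2.12, Krt18 2.57, Cd74 2.34, Hbb-bt 2.105, Hba-a1 1.71 and Gapdh 2.06. With limma on log2(FPKM + 1) the reversed log2 values were mt-Nd5 1.95, Malat1 0.67, Rps3a1 0.25, Eef1a1 2.39, Pabpc1 2.25, Hsp90ab1 1.94, Hspa8 0.92, Pkm 1.91, Ldha 1.17, Canx 0.19, Spp1 1.40, Fn1 1.51, Cd74 1.36, Hbb-bt 2.07 and Hba-a1 1.66. With limma on log2(FPKM + 5) the reversed log2 values were mt-Nd5 1.72, Malat1 0.27, Rps3a1 0.23, Eef1a1 1.72, Pabpc1 1.37, Hsp90ab1 1.22, Hspa8 0.36, Ldha 0.55, Canx 0.087, Hbb-bt 1.95 and Hba-a1 1.49. With a mean FPKM of at least 5 the reversed log2 values were Eef2 −0.84, Vim −1.20 and Actb −1.65. With no filter the reversed log2 values were Eef2 −0.17 and Actb −0.99. With quantile normalization the reversed log2 value was Hba-a1 0.23. With thinned tumour libraries the reversed log2 values were Eef1a1 1.65, Pabpc1 2.04, U6 3.48, U12 3.94, Y1 4.27, Y3 1.47, 5.8S 0.72 and U8 2.66.

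Depth limits the exosome side: 3 counts are 9.81 and 13.8 CPM there against 0.206 and 0.277 CPM in tumour, and 285 called genes had under 10 counts in both exosome libraries. A fit that leaves out a library assumes that the lone library of its group varies like the other group. For shares of 2 libraries, leaving one out always moves the mean by less than the SD, so it says nothing about stability.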

Other observations

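All tests of the small RNA classes, the histone tests limited to genes of up to 740 bases or, within a range of length, to genes at the filter level in both tumour libraries, and the test without the dominating protein-coding genes were chosen only after the result was seen, as was the bound used for genes with no exosome count.

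At equal depth, 3305 and 3127 protein-coding genes were expected in the exosome libraries and 681 and 645 in the tumour libraries. Olfactory, vomeronasal and trace amine receptor genes, 1375 genes that few tissues express, had 22 counts in the exosome libraries together and 8 in the far deeper tumour libraries.

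Of the small nuclear RNA families, U1 and U2 were higher in exosome libraries, as were RNase P RNA and 5S ribosomal RNA, while small nucleolar RNA and U5 were lower, and U6 was lower with TMM (−1.05) and higher with library totals (1.62). Transcript length is argued against as the whole cause between 100 and 159 bases. There the medians of the 2 sets differed by at least 3.71 on the log2 scale in each of 3 windows of 20 bases. From 140 bases, though, the set of small nuclear, ribosomal and ribozyme RNA itself had a median of −0.57. Length is argued against for U1, which lay 9.91 above the upper quartile of 8 small nucleolar RNAs within 20 bases of its length. For U2 and RNase P RNA, with 2 and 0 such small nucleolar RNAs, a length effect cannot be told apart from the class. No window covers small nucleolar RNAs under 100 bases, such as Snord55 (79 bases) and Snord49a (72 bases), so length was not tested for them. For the lower small nucleolar RNA, reads shared between annotated near-identical copies that had counts are argued against by genes with no such copy. Of these, 94 of 106 (88.7%) were lower and 1 higher. Copies without a count, or outside the annotated small RNA genes, were not searched, so reads shared with those stay open. That test does not cover the higher U1, U2 and 5S, with 37, 13 and 71 copies with counts. For them an effect of shared reads stays open, since the treatment of reads with several matches is not given. With small nucleolar RNA genes left out of every total, small nuclear RNA, most of it U1 and U2 in exosomes and U5 in tumour, was still 49.5% and 51.4% of exosome counts against 7.81% and 8.08% of tumour counts, a ratio of at least 6.13, so a few abundant small nucleolar RNA genes are not the whole cause. RNA isolation and library preparation that go with the groups stay open, as does sorting of RNA into exosomes, which was not tested.

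With TMM, histone genes were lower in exosome libraries than other tested genes (camera adjusted p = 7.33e-07, and adjusted p = 0.330 with an estimated correlation), with 37 of 43 called lower, against 6 with library totals. An effect of short length cannot be told apart, since 406 other protein-coding genes of 312 to 6940 bases had a median of 0.039 and 24 of up to 740 bases a median of −0.33, which the bound set in advance for the first would read against length, but that bound left out that the filter admits most of these genes on exosome counts, with only 223 of 911 at the filter level in both tumour libraries. At that level, 117 of the genes in the first range had a median of −0.86 and a lower quartile of −1.84, against a histone median of −2.63, and 7 of up to 740 bases had −2.03 and −3.99, against −2.73. The filter itself cannot be told apart from a real difference, because all 223 had a median of −0.94 and a lower quartile of −1.81, while the fitted values of −0.99 and −2.03, against −4.20 for histones, would have excluded it by the bound set in advance but are no bounds for genes with no exosome count and were replaced after the result was seen. A biological difference in the release of histone messenger RNA was not tested.

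More protein-coding genes were seen in exosome libraries at equal depth. A candidate explanation is a few protein-coding genes, or small RNA reads assigned to them, taking most tumour protein-coding counts, since with the 20 genes of highest count in any library and all that overlap annotated small RNA genes left out, 2751 and 2569 genes were expected in exosomes and 2338 and 2309 in tumour at 4023 counts, where the highest tumour number was 0.910 of the lowest exosome number. At 7160 protein-coding counts with no gene left out that ratio was 0.402, which by the bound set in advance would have argued against noncoding RNA taking the tumour counts, but the bound took protein-coding counts to be free of such reads, and Snrpb alone held 65.1% and 67.2% of them in tumour, so this cannot be told apart. Genomic DNA as the whole source is argued against, because receptor genes would then hold 828 exosome counts by their exon length, and the 22 observed were 0.0266 of that (95% limits 0.0167 to 0.0402), while in tumour the ratio was 3.85e-04. No biological explanation was tested.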
